A study of Rattus norvegicus with 10 samples.

How the data were processed

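RNA was collected 48 h after seeding from RCS cells, a rat chondrosarcoma line that makes a cartilage-like matrix, and from RCS cells in which ARSL (arylsulfatase L, a sulfatase of the secretory pathway) had been knocked out. There were 5 wild-type (WT) and 5 ARSL knockout (KO) libraries, which the labels call biological replicates. The labels state neither whether the KO libraries came from 1 clone or from several, nor the days of culture, so a difference between genotypes cannot be told apart from a difference between the lines that has another origin. Libraries were made with a commercial digital mRNA-seq service per the labels' protocols. Reads were handled with bcl2fastq, STAR 2.7.11a and HTSeq on the rat build rn6 per the submitters' processing notes. The use of strand in counting is not given in the sources used here.

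The authors deposited 1 table of 10184 genes by 10 libraries with values on a variance-stabilized, log2-like scale, normalized for library size. The tool that made these log2-like values and the filter on genes are not given in the sources used here. The lowest value, 4.42, was shared by all libraries and is that of a count of 0. On this scale a difference understates the fold change of weakly expressed genes, so normalised reads are given beside it. Inverting the closed form of the transformation put every value of every library on a whole-read step, with a largest departure of 1.6e-09 reads. The recovered reads gave 2065594 to 2591819 reads per library over the listed genes. These totals cover the listed genes only, in which every gene had at least 30 reads in total and a read in at least 3 libraries. Normalised reads are recovered reads divided by the library's size factor. No row carried the symbol Arsl or Arse, and 813 rows had no symbol, so the targeted gene was not analysed here and the genotype labels were not checked against it.

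Genes with a mean at least 1 above the lowest value, about 10.7 normalised reads, were tested, 8431 in all. The difference KO minus WT was tested with limma 3.58.1 in R 4.3.3 on the deposited log2-like values, with empirical Bayes variance estimates and an intensity trend, two-sided, and Benjamini-Hochberg adjustment over the tested genes. Calls are genes with an adjusted p under 0.05. The 33 gene lists, with 756 entries, were fixed before the data were examined, as were the main test, the alternative settings and the rule for named genes. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. The rule named Arsl, then the 10 largest rises and the 10 largest falls among calls whose KO values lay entirely above or below the WT values and whose symbol was no placeholder. From each list it named up to 2 called rises and 2 called falls by size, or, where no member was called, the member with the smallest p; 1 gene so named is not reported here. Measures of single libraries were compared with exact permutation tests of the difference of means over the 252 assignments, whose smallest two-sided p is 0.0079. Figures were drawn with matplotlib 3.10.9.

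Libraries of a group were compared with a chi-square of their reads over genes with at least 20 reads in the pair. The lowest value per degree of freedom, 1.85, was that of WT 1 and WT 2, above the sampling noise, and all 10 libraries were kept as separate samples. WT 3 and WT 4 had 2.37 with each other but 15.7 to 21.3 with the other WT libraries. A value above the sampling noise does not show that the cultures were independent. The fits were tested on simulated data, with 200 of 8431 genes changed in each of 5 simulations of KO against WT. Of the changed genes, 30.9% were called at a fold of 1.5, 72.6% at a fold of 2 and 91.3% at a fold of 4, and 3.3% of the calls were false. A shifted list was found in 5 of 5 simulations and 1 unshifted list was called. The simulated genes varied independently of each other, and the simulated lists held random genes. In the real libraries genes vary together, with an estimated inter-gene correlation of up to 0.79 in a list. The simulated rates of false calls and of list calls therefore need not hold for the real data.

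The settings chosen beforehand were a block by replicate number, no filter and a stricter filter, median centring, quantile normalization, no intensity trend, robust variance estimates, array quality weights, an exact Wilcoxon test, limma-voom on the recovered reads and leaving out each library in turn. Leaving out 3 libraries together and a covariate for the main axis of variation within groups were added after seeing the data. Gene order came from RefSeq names on another rat assembly, GRCr8, and was used only to find which genes neighbour each other; 7804 of the tested genes, 92.6%, were placed by symbol or synonym, and no coordinates are given.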

Results

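The data comprised mRNA profiles of 5 WT and 5 ARSL KO libraries of RCS chondrosarcoma cells, taken 48 h after seeding. The single comparison the design makes is KO against WT, which asks how loss of ARSL alters gene expression in these cells. Recovered reads per library averaged 2327000 ± 196000 in WT and 2260000 ± 180000 in KO (SD, n = 5 each; exact permutation test, two-sided p = 0.563). The 10 most abundant genes took 13.94 ± 0.285% of reads in WT and 11.78 ± 1.4% in KO (SD, n = 5 each; exact permutation p = 0.032, 0.178 after Benjamini-Hochberg adjustment over 6 library measures). Genes whose symbol begins with Mt- took 5.619 ± 0.995% of reads in WT and 4.623 ± 0.552% in KO (SD, n = 5 each, exact permutation p = 0.119, adjusted 0.178). Rows without such a symbol were not counted in this share, mitochondrial or not. Among them were the most abundant row, which has no symbol, with 4.62% of all reads, and AY172581.9 with 1.17%. The share can therefore understate the mitochondrial reads.

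The first principal component held 51.1% of the variance and did not follow genotype. WT 3 and WT 4 scored 28 and 26.8 on it and ARSL KO 4 scored 7.9, while the other 7 libraries lay between -15 and -3. The second component, with 13.3%, parted the genotypes, with WT at 1.4 to 10.6 and KO at -9.1 to -3.7.

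**Figure D1:**
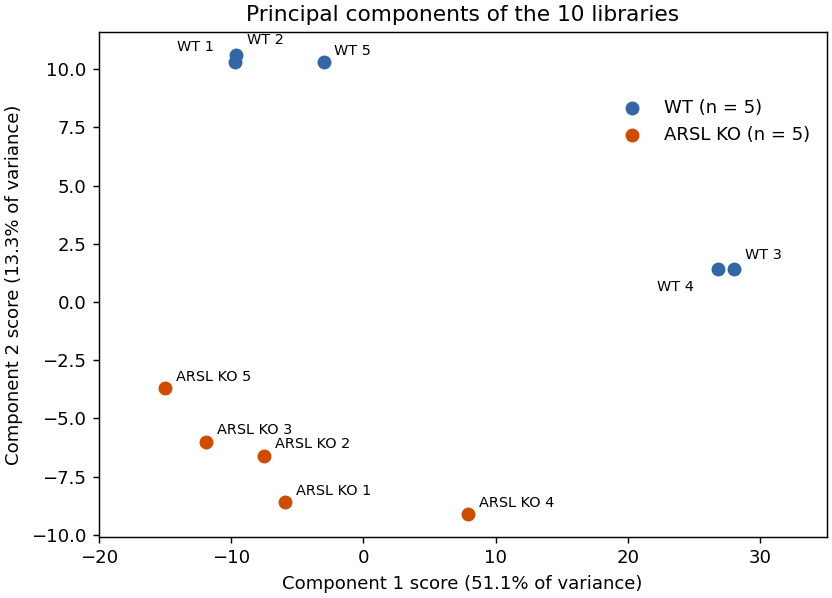
Scores of the 10 libraries on principal components 1 (51.1% of variance) and 2 (13.3%), coloured by genotype, 1 point per library. WT 3 and WT 4 lie at 28 and 26.8 on component 1 and ARSL KO 4 at 7.9, and all KO libraries lie below all WT libraries on component 2.

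Cspg4, which encodes the cell-surface chondroitin sulfate proteoglycan NG2, had the largest rise in KO cells. It went from 17.49 ± 5.22 to 185.3 ± 45.9 normalised reads (SD, n = 5 each), 10.6-fold, with a difference of 2.12 ± 0.143 on the log2-like scale (SE; limma adjusted p = 3.34e-06). Ecrg4, which encodes a secreted peptide precursor, fell by 1.74 on that scale, from 7160 ± 3480 to 1966 ± 448 normalised reads, 3.64-fold (limma adjusted p = 0.00569; 2.44-fold without the 3 libraries high on component 1). A pair of cartilage matrix genes also fell. Col11a1, a chain of the fibrillar collagen XI, fell by 1.16 (SE 0.229), 2.38-fold in normalised reads but 1.81-fold without those 3 libraries. Ucma, a small secreted cartilage protein, fell by 1.16 (SE 0.212), 7.04-fold in normalised reads but 4.48-fold without those 3 libraries. It went from 50.17 to 7.124 normalised reads, near the lower limit of the table in KO, so the size of its fold is uncertain. In all, 96 of 8431 genes passed the limma test, of which 22 rose and 74 fell, and 15 differed by at least 1 on the log2-like scale, 4 upward and 11 downward.

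Among the other large rises, Cavin3, a caveola coat protein, rose by 1.39 (SE 0.232), from 121.5 to 349.4 normalised reads. Ltbr, the lymphotoxin beta receptor, rose by 1.08 (SE 0.136), and Armcx2 also by 1.08 (SE 0.13). Duox2, an NADPH oxidase that makes hydrogen peroxide, rose from 490.6 to 984.3 normalised reads. Cgref1, Cybrd1, Npepl1, Ldhb and Filip1 rose by 1.00, 0.99, 0.81, 0.80 and 0.74 on the log2-like scale. Cybrd1 encodes a ferric reductase and Ldhb a subunit of lactate dehydrogenase. Npepl1 and Ldhb were near the lower limit of the table in WT, at 5.349 and 4.752 normalised reads. The call of Duox2 was lost without ARSL KO 2, 3 or 5 (adjusted p up to 0.062), that of Cybrd1 without ARSL KO 3 (0.055) and that of Npepl1 without ARSL KO 2 (0.05).

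Among the other large falls, Mgst2, a microsomal glutathione transferase, fell by 1.74 (SE 0.318) and Gsta1, a cytosolic one, by 1.12 (SE 0.124). Gsta1 belongs to a family of similar genes, and how the authors' counting shared reads among them is not given, so its value is uncertain. S100a6, a calcium-binding protein, fell by 1.36 (SE 0.157). Atp1b1, the beta subunit of the sodium pump, fell by 1.25 (SE 0.138). PCOLCE2, an enhancer of procollagen processing, fell from 1936 to 772.2 normalised reads. Wnt8a fell by 1.12 (SE 0.169) and Marcks by 1.11 (SE 0.162). The call of Mgst2 was lost without ARSL KO 3 (adjusted p 0.066) and that of PCOLCE2 without ARSL KO 2, 3 or 5 (up to 0.083). Without the 3 libraries high on component 1, the fall in normalised reads went from 4.24-fold to 3.09-fold for Mgst2 and from 2.51-fold to 1.77-fold for PCOLCE2. It went from 2.88-fold to 2.61-fold for Atp1b1, and was larger than with all libraries for S100a6, Gsta1, Wnt8a and Marcks.

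**Figure D2:**
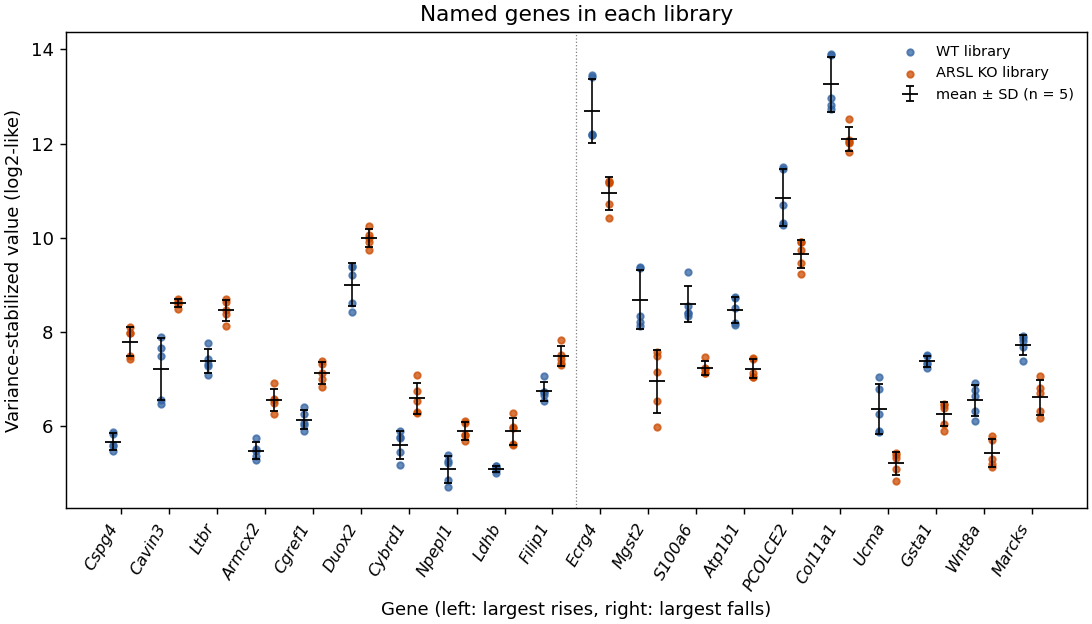
Variance-stabilized value (log2-like) of the 10 genes with the largest rises and the 10 with the largest falls, 1 point per library, with the mean and SD of 5 libraries per genotype. KO and WT libraries do not overlap for any of these genes, which is part of the rule that chose them; Cspg4 differs most, by 2.12.

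Of the 96 calls, 91 had KO values entirely above or below the WT values, as did 359 of all tested genes, where chance gives 0.79% of genes. At an unadjusted p under 0.05 there were 1136 genes, against 422 by chance. The count fell to 62 without WT 3, 53 without ARSL KO 1, 37 without ARSL KO 2, 33 without ARSL KO 3 and 37 without ARSL KO 5. An exact Wilcoxon test called 0, but its smallest p, 0.0079, would need 1339 completely separated genes for any call, so that result says nothing about stability. With WT 3, WT 4 and ARSL KO 4 left out together, an alternative chosen after seeing the data, 300 genes passed, 113 rising and 187 falling, and 91 of the 96 calls were kept.

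The lists closest to the function of ARSL held 0 or 1 call each. With 96 of 8431 genes called, few calls are expected in lists this short. These counts therefore do not show that such genes were spared. Of 6 tested sulfatases and their activators, 0 were called (0 adjusted over the list alone; list adjusted p = 0.99), and the member with the smallest p, Sumf1, which activates sulfatases, differed by 0.18 (SE 0.098, limma adjusted p = 0.455). The list's median was -0.02 while its test pointed up. Among 22 tested genes of glycosaminoglycan chain synthesis, Ugdh rose, from 643.8 ± 83.7 to 988.8 ± 105 normalised reads, and 21 did not pass (2 adjusted over the list alone; list adjusted p = 0.99). Ugdh makes UDP-glucuronic acid, a building block of these chains. Among 15 genes of sulfate supply and sulfotransferases, Chst11, a chondroitin 4-sulfotransferase, rose from 417.8 ± 32.3 to 586.1 ± 56 normalised reads, and 14 did not pass (1 adjusted over the list alone; list adjusted p = 0.71). That list had a median of -0.03 and a mean of 0.03. The call of Ugdh was lost without ARSL KO 3 (adjusted p up to 0.059 over the fits with 1 library left out) or ARSL KO 5, and that of Chst11 without WT 3, WT 5 or ARSL KO 2, 3, 4 or 5 (up to 0.098).

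In the cartilage matrix list, 2 of 19 tested members fell, Col11a1 and Ucma, and 17 did not pass (4 adjusted over the list alone). The abundant Acan and Col2a1 differed by 0.22 (SE 0.18, limma adjusted p = 0.616) and -0.20 (SE 0.175, 0.635). The list passed in the downward direction (median -0.20, adjusted p = 0.0032; adjusted p = 0.78 with an estimated correlation). WT 3 and WT 4 had list means of 0.566 and 0.571 and the other 8 libraries lay between -0.316 and 0.064; without the 3 libraries high on component 1 the median was 0.10 and the adjusted p 0.65. The call of the list was lost without WT 3 or WT 4 (adjusted p up to 0.16). That of Col11a1 was lost without ARSL KO 1, 2, 3 or 5 (up to 0.083) and that of Ucma without ARSL KO 3 or 5 (up to 0.062).

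In the lysosome list, Manba, a lysosomal mannosidase, fell by 0.85 (SE 0.175), and 35 of 36 members did not pass (2 adjusted over the list alone). The list passed in the downward direction (median -0.15, adjusted p = 0.0025; adjusted p = 0.78 with an estimated correlation). Its means were 0.428 in WT 3, 0.444 in WT 4 and 0.087 in ARSL KO 4, above all other libraries, and without these 3 the median was 0.04 and the adjusted p 0.72. The cell cycle list passed upward (median 0.24 over 28 members, adjusted p = 0.00045; adjusted p = 0.78 with an estimated correlation) with 0 members called (0 adjusted over the list alone). Plk1, a mitotic kinase with the smallest p of that list, differed by 0.38 (SE 0.14, limma adjusted p = 0.236). The cell cycle means were -0.443 in WT 3, -0.474 in WT 4 and -0.147 in ARSL KO 4, below all others, and without these 3 the median was 0.05 and the adjusted p 0.6. The call of the lysosome list was also lost without WT 3 or WT 4 (adjusted p up to 0.16), and that of Manba without WT 3, WT 4 or ARSL KO 1, 2, 3 or 5 (up to 0.1).

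The mitochondrially encoded genes, fibroblast and dedifferentiation markers and p53 targets passed both with all libraries and without those 3, with the preset correlation only. WT 3 and WT 4 had means of 0.540 and 0.478 for the fibroblast list, where the other WT libraries lay between -0.045 and 0.197, and of -0.107 and -0.090 for the mitochondrial list, where the other WT libraries lay between 0.270 and 0.313. Mitochondrially encoded genes had a median of -0.30 over 12 members (adjusted p = 0.00045; adjusted p = 0.78 with an estimated correlation), with 0 called (2 adjusted over the list alone). Mt-co3, a subunit of cytochrome c oxidase, had 10110 ± 572 normalised reads in WT and 7615 ± 1180 in KO (SD, n = 5 each; limma adjusted p = 0.139). The list did not pass after quantile normalization (adjusted p = 0.098). Without the 3 libraries its median was -0.52 (adjusted p = 4.2e-15; adjusted p = 0.22 with an estimated correlation). In the fibroblast and dedifferentiation list, Col6a2, a collagen VI chain, fell by 1.11 (SE 0.21) and S100a4 by 0.60 (SE 0.112), and 6 of 8 members did not pass (5 adjusted over the list alone; list median -0.56, adjusted p = 0.00045; adjusted p = 0.7 with an estimated correlation). Without the 3 libraries the median of this list was -0.37 (adjusted p = 0.00052; adjusted p = 0.7 with an estimated correlation). The p53 targets had a median of 0.31 over 10 members with 0 called (4 adjusted over the list alone; list adjusted p = 0.0025; adjusted p = 0.18 with an estimated correlation; fry adjusted p = 0.018). Without the 3 libraries their median was 0.25 (adjusted p = 0.00062; adjusted p = 0.22 with an estimated correlation). The p53 list did not pass with the stricter filter (adjusted p = 0.23), which left too few fibroblast and dedifferentiation markers to test. Aen, a nuclease of the p53 list, differed by 0.46 (SE 0.125, limma adjusted p = 0.108). The call of Col6a2 was lost without ARSL KO 2, 3 or 5 (adjusted p up to 0.075) and that of S100a4 without ARSL KO 1 or 3 (up to 0.061). Without the 3 libraries Col6a2 fell by 0.92 and S100a4 by 0.71.

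**Figure D3:**
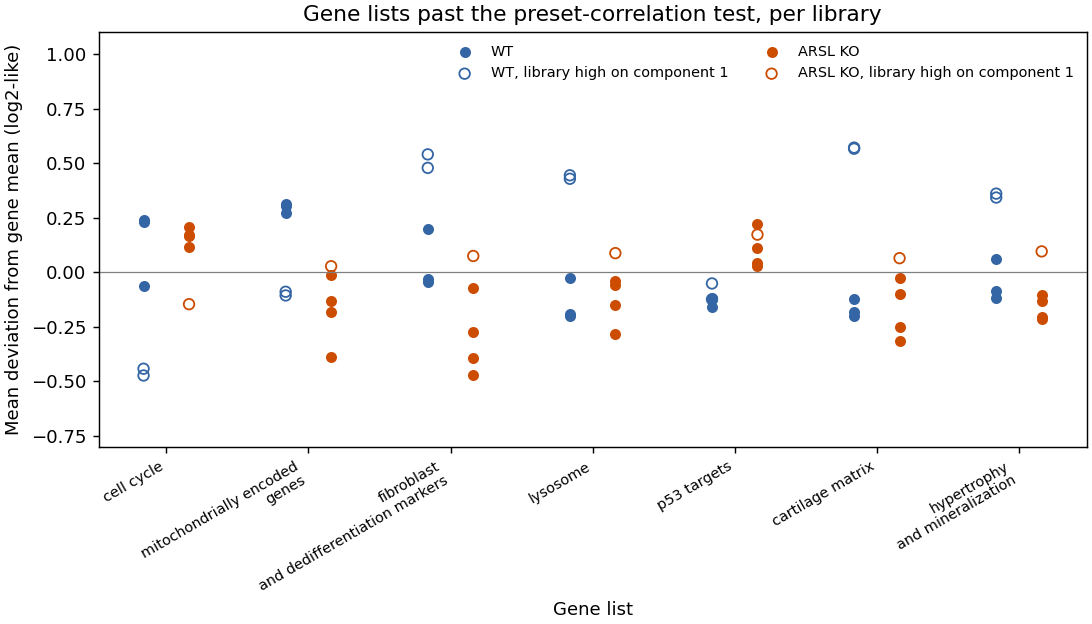
Mean deviation of the members of 7 gene lists from each gene's mean over the 10 libraries (log2-like scale), 1 point per library; open circles are WT 3, WT 4 and ARSL KO 4. For cell cycle, lysosome and cartilage matrix the open WT circles lie farthest out, at -0.443 and -0.474 for cell cycle.

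In the hypertrophy and mineralization list, Mef2c, a transcription factor of hypertrophic chondrocytes, fell by 0.65 (SE 0.13), and 10 of 11 members did not pass (3 adjusted over the list alone; list median -0.23, adjusted p = 0.0041; adjusted p = 0.77 with an estimated correlation). The list means of WT 3 and WT 4 were 0.360 and 0.342, above all other libraries, and without the 3 libraries the median was -0.08 and the adjusted p 0.051, with 4 members that fell. With array weights the cartilage matrix, lysosome, cell cycle and hypertrophy lists did not pass (adjusted p = 0.81, 0.82, 0.42 and 0.051). The weights were 0.32 for WT 3, 0.35 for WT 4 and 0.71 for ARSL KO 4, against 1.14 to 1.72 for the other libraries. That setting thus counts the same 3 libraries least and is not separate from leaving them out. Of the 28 lists, 7 passed with the preset correlation, 2 upward and 5 downward, 0 with an estimated correlation and 1 with fry, which tests a list's net direction without comparing it with other genes. The fry test for change in either direction passed for 5 lists: cell adhesion and cell-surface proteoglycans (adjusted p = 4.7e-07), fibroblast and dedifferentiation markers (0.00033), glycosaminoglycan chain synthesis (0.00053), BMP and TGF-beta targets (0.014) and p53 targets (0.029). Such a pass can rest on few strong members and need not mean a change across the list. Cspg4 was the 1 call of the adhesion list and Ugdh the 1 call of the glycosaminoglycan list. The call of Mef2c was lost without WT 3, 4 or 5 or ARSL KO 1, 2, 3 or 5 (adjusted p up to 0.088).

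Lists that did not pass held 4 further calls among the named genes. Tgfbi, an extracellular protein induced by TGF-beta, fell by 0.71 (SE 0.113) in the BMP and TGF-beta list, where 12 of 13 members did not pass (5 adjusted over the list alone; list adjusted p = 0.99). Sdf2l1, an endoplasmic reticulum protein, fell by 0.71 (SE 0.145) in the unfolded protein response list, where 27 of 28 did not pass (1 adjusted over the list alone; list adjusted p = 0.5). Atf3, a stress-induced transcription factor, fell by 0.64 (SE 0.139) among 5 immediate early genes (2 adjusted over the list alone; list adjusted p = 0.99). Gli1, a transcription factor and target of hedgehog signalling, rose from 183.3 ± 8.97 to 256.5 ± 9.96 normalised reads, in a list with 3 tested members, too few for the list test (1 adjusted over the list alone). Cspg4 was the 1 call of 15 adhesion and cell-surface proteoglycan genes (4 adjusted over the list alone; list adjusted p = 0.99), whose mean was 0.08 while the test pointed down. Of these calls, that of Sdf2l1 was lost without WT 3 or 4 or ARSL KO 1, 2, 3 or 5 (adjusted p up to 0.099), that of Atf3 without WT 3, 4 or 5 or ARSL KO 1, 2, 3 or 5 (up to 0.13), and that of Gli1 without WT 5 or ARSL KO 1, 2, 3 or 5 (up to 0.066).

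The remaining lists held 0 calls. Mia3, which serves collagen export, differed by -0.30 (SE 0.098) in the list of collagen folding, export and processing (24 members, 0 adjusted over the list alone; list adjusted p = 0.71, but 0.002 upward without the 3 libraries, and then adjusted p = 0.7 with an estimated correlation). Tmem165, a Golgi manganese transporter, differed by 0.42 (SE 0.11) in the Golgi list (33 members, 0 adjusted over the list alone; list adjusted p = 0.57), and Ulk2 by -0.24 (SE 0.101) in the autophagy list (28 members, 0 adjusted over the list alone; list adjusted p = 0.57). The 11 interferon response genes had a median of -0.21 (1 adjusted over the list alone; list adjusted p = 0.11), with means of 0.590 in WT 3 and 0.620 in WT 4, and the median was 0.12 without the 3 libraries. Rpl12 differed by 0.39 (SE 0.101) among 21 ribosomal protein genes (1 adjusted over the list alone; list adjusted p = 0.11). Dlx5 differed by 0.42 (SE 0.115) among 5 osteoblast markers (3 adjusted over the list alone; list adjusted p = 0.25), opposite to the other 4 and to the list's median of -0.34, Timp3 by -0.47 (SE 0.139) among 6 matrix proteases and inhibitors (3 adjusted over the list alone; 0.22) and Epha4 by -0.42 (SE 0.126) among 8 FGF and MAPK targets (1 adjusted over the list alone; 0.069). Gas6 differed by -0.76 (SE 0.25) among 7 vitamin K cycle genes (list adjusted p = 0.99), Hsd17b7 by -0.52 (SE 0.172) among 16 cholesterol synthesis genes (0.5) and Shox2 by 0.26 (SE 0.097) among 10 chondrocyte transcription factors (0.99). The cholesterol synthesis list passed upward, opposite to Hsd17b7, without the 3 libraries (adjusted p = 2.6e-05; adjusted p = 0.7 with an estimated correlation) and with array weights (adjusted p = 0.0083), and the ribosomal protein list passed upward without the 3 libraries (adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation), with array weights (0.019), without WT 5 (0.033) and without ARSL KO 5 (0.021). Adm differed by -0.20 (SE 0.134) among 13 hypoxia and glycolysis genes (list adjusted p = 0.11), Cox5b by -0.19 (SE 0.085) among 24 nuclear genes of oxidative phosphorylation (0.99) and Me1 by -0.31 (SE 0.164) among 12 NRF2 targets (0.28), of which 10 lay above 0. The hypoxia list had a median of -0.15, which was 0.14 without the 3 libraries. Some lists passed downward under single alternatives, among them the first residual component as covariate, chosen after seeing the data. That covariate was drawn from the same values and lowers the spread within groups, so passes with it are no separate support. The FGF and MAPK list did so without WT 1 (adjusted p = 0.016), WT 2 (0.024), ARSL KO 1 (0.047) or ARSL KO 4 (0.039) and with the covariate (0.029). The interferon list did so with no filter (0.047), without WT 1 (0.034), WT 2 (0.024) or WT 5 (0.044) and with the covariate (0.019). The hypoxia list did so without WT 1 (0.03), WT 5 (0.031) or ARSL KO 1 (0.047) and with the covariate (0.032). The passes of the FGF and MAPK, interferon and hypoxia lists used the preset correlation. With all libraries and an estimated correlation, the camera adjusted p was 0.78 for each of them. Without the 3 libraries 6 named genes that had no call passed: Mia3 (limma adjusted p = 0.0244), Tmem165 (0.031), Rpl12 (0.0237), Dlx5 (0.0464), Shox2 (0.0338) and Mt-co3 (0.0087). With array weights 4 of these passed, with the covariate 15 such genes and without ARSL KO 4 Tmem165. Adjusted over the list alone, 0 members passed in the lists of Gas6, Hsd17b7, Shox2, Adm, Cox5b and Me1. Markers of other cell types were too few for a list test: 2 macrophage and leukocyte markers, with Cd14 at 0.09 (SE 0.095), 2 endothelial markers, with Vwf at -0.30 (SE 0.169), and 1 adipocyte marker, Scd, at 0.01 (SE 0.159). Ccnd1, the 1 tested WNT target, differed by 0.17 (SE 0.188).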

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

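The tests of depth and of growth for the 3 libraries, and that of the medians and called members of lists without them, were chosen after the result was seen. A value was picked out here when 1 library of a group of 5 lay far from the other 4, by a gap of more than 0.71 of the group's range. That held for 9 of 172 pairs of a result and a group, where chance gives about 8.6, so the number of such pairs is no larger than chance. S100a6 in WT 5 was 9.27, against 8.331 to 8.559 in the other WT libraries. Mt-co3 in ARSL KO 3 was 12.45, against 12.95 to 13.06. The share of reads of genes whose symbol begins with Mt- was 3.671% in that library, against 4.64 to 5.029%. Plk1 in ARSL KO 3 was 9.607, against 9.214 to 9.32, and Cox5b in ARSL KO 5 was 10.9, against 11 to 11.04. In ARSL KO 4, Mef2c was 8.487, against 7.918 to 8.073, and the list means were 0.206 for chondrocyte transcription factors, 0.072 for sulfate supply and sulfotransferases and -0.147 for the cell cycle, against -0.094 to -0.056, -0.008 to 0.004 and 0.116 to 0.206 in the other KO libraries.

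WT 3, WT 4 and ARSL KO 4 stood apart on the first component. Sequencing depth is argued against, since the totals of all 3 libraries lay inside the range of the other 7. So is a wrong genotype: on the 300 genes called in the other 7 libraries, with WT set at 0 and KO at 1, they lay at 0.21, 0.24 and 0.84, and all 3 were nearer to their labelled genotype. Slower growth or a denser state of those cultures may account for the pattern, as all 3 had a lower cell cycle mean and a higher lysosome mean than each of the other 7. This was found and tested on the same data, and a difference of culture day or handling stays open because the labels give none.

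Of the 7 lists past adjusted p 0.05 with the preset correlation (0 with an estimated correlation), the uneven number of these libraries, 2 in WT and 1 in KO, may account for some. Without them 3 stayed past it in their direction, mitochondrially encoded genes, fibroblast and dedifferentiation markers and p53 targets (adjusted p = 0.22, 0.7 and 0.22 with an estimated correlation), with medians of -0.52, -0.37 and 0.25, and 0 of these 3 medians fell under 0.5 of its size or changed sign, which argues against the uneven number as their whole cause. The medians of cartilage matrix, lysosome, cell cycle and hypertrophy and mineralization went from -0.20, -0.15, 0.24 and -0.23 to 0.10, 0.04, 0.05 and -0.08, with adjusted p of 0.65, 0.72, 0.6 and 0.051. In 2 of these 4, cartilage matrix and cell cycle, no more members were called in the direction of the list than with all libraries, in line with a shift carried by those libraries. Lysosome went from 1 to 2 members that fell, with 1 that rose, and hypertrophy and mineralization from 1 to 4 that fell. Calls over all genes went from 96 to 300 at the same time. The cause stays open for these 2 lists. Cell cycle and hypertrophy and mineralization each passed in 10 of 10 fits with 1 library left out. No such fit removes both WT 3 and WT 4, so these passes cannot decide whether those libraries carried the shift.

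Of 100 splits of the 10 libraries into 5 and 5, 2 called at least 96 genes, the count of the real split, which is 1 of the 2. Chance is thus an unlikely source of the count but is not excluded. The other such split called 346 genes and had the 3 libraries on 1 side, so a grouping other than genotype can give such a count. Of the 16 splits that kept the 3 libraries together, it was the only 1 with as many genes as the real split. Of the 84 splits that parted the 3 libraries, no split but the real one called any gene. A called difference of at least 1 was reached by 15 genes in the real split and at most 9 in another, so that 1 of 100 splits gave as many. For gene lists chance cannot be excluded: 37 of 100 splits gave at least 7, and the highest other gave 15.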

How the results depend on the processing

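Leaving out WT 3, WT 4 and ARSL KO 4 together and the covariate were chosen after seeing the data. None of the 96 calls changed sign under any alternative, but this was largely fixed in advance and says little about stability. The filters, replicate block, variance settings, Wilcoxon test and covariate leave each difference as it was. In 91 of the calls the genotypes separate completely, so leaving out or weighting libraries cannot reverse them. Counts of calls stayed within 1.5 times the reported value with no filter, median centring, quantile normalization, no intensity trend, robust variance estimates and the replicate block. The causes of the following shifts were not tested, with 2 exceptions. The stricter filter tested fewer genes (3180), and the covariate takes out spread within groups. With the stricter filter 42 genes passed (12 rose, 30 fell, 9 by at least 1). Array weights, lowest for WT 3, WT 4 and ARSL KO 4, gave 219 (79 rose, 140 fell), so that 36.1% rose against 22.9%. The exact Wilcoxon test gave 0 (0 rose, 0 fell, 0 by at least 1; 821 at an unadjusted p under 0.05, smallest adjusted p 0.19), where 1339 completely separated genes would be needed for a call and 359 were. With limma-voom on recovered reads 88 genes passed (87 of the 96 kept; of the named calls Atf3 was lost, adjusted p = 0.0562), and 44 by at least 1, on a scale that does not compress weak genes. Without the 3 libraries 300 passed (113 rose, 187 fell), and with the covariate 1345 (687 rose, 658 fell). The covariate was computed from the same values after group means were removed. It leaves each difference unchanged and lowers the spread it is tested against, so the higher count is no separate support. Leaving out 1 library gave 33 to 101 calls (8 to 24 rose, 25 to 78 fell, 11 to 18 by at least 1) and 5 to 10 lists. Of 30 named calls, 14 held in each such fit, and 15 were lost without ARSL KO 3; all 30 held without the 3 libraries. The lists past the threshold were 0 with an estimated correlation and 1 with fry, and no list test was run with robust variance estimates or the Wilcoxon test. The mitochondrially encoded list did not pass after quantile normalization. For Arsl nothing was run, as it was not analysed here. Replicate numbers did not pair the libraries (correlations of deviations -0.06, 0.07, -0.29, 0.59 and 0.26); with the replicate block 136 genes passed (32 rose, 104 fell, 17 by at least 1; 7 lists), with 89 of the 96 kept. Among named genes, none of them called, Scd at 0.008 turned to -0.014 under quantile normalization; it ranged from -0.101 to 0.095 with 1 library left out, below 0 without WT 1 (-0.013), WT 2 (-0.026), WT 5 (-0.101), ARSL KO 1 (-0.032) or ARSL KO 2 (-0.085), and Me1 turned to 0.021 without the 3 libraries. At this depth the simulated fits called 30.9% of changes of 1.5-fold, so smaller changes can be missed.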

Other observations

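The genes in the next 2 paragraphs were chosen after their values were seen. Cavin1, the main caveola coat protein, fell by 0.81 (SE 0.15, limma adjusted p = 0.0183), from 774.7 to 413 normalised reads, opposite to Cavin3. Cald1, an actin-binding protein, fell by 0.87 (SE 0.164, limma adjusted p = 0.0184). Vdr, the vitamin D receptor, fell from 168.3 to 93.94 normalised reads (limma adjusted p = 0.00983), and Irx1 and Foxn4, both transcription factors, fell by 0.95 and 0.67. Nfkbia, an inhibitor of NF-kappa-B, rose by 0.47 (SE 0.092, limma adjusted p = 0.0207), and Tnfaip6, a hyaluronan-binding protein induced by inflammation, rose by 0.59 (SE 0.127, 0.0384). The call of Tnfaip6 was lost without WT 3, WT 4 and ARSL KO 4 (adjusted p = 0.0733).

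Without WT 3, WT 4 and ARSL KO 4, 8 of 12 mitochondrially encoded genes fell, among them Mt-nd5 by 0.58 (SE 0.092, limma adjusted p = 0.000273) and Mt-cyb by 0.65 (SE 0.114, 0.00101). With all 10 libraries 0 of the 12 were called. Genes with an Mt- symbol took 4.589% of reads in WT 3 and 4.474% in WT 4, inside the KO range of 3.671 to 5.029%. The other WT libraries had 6.262 to 6.409%. These calls thus depend on leaving out the WT libraries nearest to KO. In the 7 libraries left, 3 further lists passed upward. They were cholesterol synthesis (median 0.22, adjusted p = 2.6e-05; adjusted p = 0.7 with an estimated correlation), with 2 members that rose, and collagen folding, export and processing (median 0.13, adjusted p = 0.002; adjusted p = 0.7 with an estimated correlation), with 4 that rose and 1 that fell. The third was ribosomal proteins (median 0.09, adjusted p = 0.036; adjusted p = 0.75 with an estimated correlation), with 2 that rose. With all 10 libraries the median of the collagen folding list was -0.05 and its test pointed down.

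Runs of neighbouring genes were shifted between genotypes, a pattern noticed in the data first; the window and the tests were set afterwards. Running medians over 31 genes passed a threshold of 0.173, from 1000 shuffles, in 9 runs, 8 lower and 1 higher in KO, with 715 genes. The higher run, from Mtf2 to Anapc4, had a median of 0.20 over 105 genes and holds Ugdh. The lower run from Evi5l to Rcc1l had a median of -0.19 over 121 genes and 6 calls, and the run from Cenpl to Cd46 one of -0.18 over 108 genes and 4 calls. Of 89 placed calls, 22 lay in runs, each with the direction of its run, against 9.2% of placed genes; since calls helped to set the runs, this share is no independent evidence. Ecrg4, Atp1b1, Gsta1, Wnt8a, Ugdh and Atf3 were the named calls in runs.

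Reads shared by overlapping neighbours are argued against, because the correlation across genes of differences 5 to 10 places apart was 0.76 of that between adjacent genes (0.088 against 0.115; genes are not independent replicates). Regional regulation that goes with a state of the culture other than genotype is argued against too: 1 of 100 splits, the real one, gave as high a correlation, with 0.082 the highest of the others. That other split had 4 WT libraries on 1 side and is thus close to the real one. A culture state that differed between all WT and all KO libraries would give the same result, so the splits cannot decide on it. A copy-number or other regional difference between the lines, with or without a link to ARSL, may account for the runs. When runs were set anew on every other gene, only 4 passed: Bcl3 to Prx, Suco to Tstd1, Brox to C13h1orf74 and Rchy1 to Nfxl1. All 4 kept their direction in the genes left out, with medians of -0.18, -0.15, -0.17 and 0.21 (adjusted shuffle p of 0.002 to 0.004). These 4 have other first and last genes than the 9 runs above, so the 9 were not each tested on genes left out. Their overlap with the 9 is not given here, and they need not be separate regions. DNA was not measured here, and the number of clones is not stated, so this stays a hypothesis.

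Glutathione transferase genes were tested as a family because 3 of them, Mgst2, Gsta1 and Gstt1, were among the calls. The call of Gstt1 was lost without WT 3, WT 4 and ARSL KO 4 (adjusted p = 0.0575). The median of the 9 tested members was -0.35, at percentile 0 of 10000 random sets matched on mean value, with 5 members below 0 and 4 above. Because the called genes raised the question and are part of the family, and the members went both ways, whether the whole family shifted cannot be told apart from a fall of some members.

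The tested genes nearest to the place of Arsl in the gene order, Dcun1d1, Mccc1, Acad9, Anxa5, Exosc9 and Ccna2, differed by -0.04, -0.12, 0.33, -0.26, 0.17 and 0.27, with 0 called.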
